A study of Mus musculus with 12 samples.

How the data were processed

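RNA from adult mouse whole cortex was measured in 12 libraries of 3 Tet1 genotypes (WT, HxD and KO, 4 libraries each), grouped by the genotype in the sample labels. Total RNA was column-purified, mRNA was selected on oligo d(T) beads and libraries were sequenced on a NovaSeq instrument, per the labels' protocols. FastQC, Trim Galore 0.6.7, STAR 2.7.1a, SAMtools 1.9 and StringTie 2.2.3 are named, per the submitters' processing notes, as are the builds GRCm39 and mm10, without role or order. No coordinates are therefore given. How reads were assigned to genes, the strand setting and any filter are not given in the sources used here.

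The deposited table holds 1 estimated count per gene symbol and library, which the authors left without normalization, and the values are whole numbers, so rounding to whole numbers changed nothing. It was read as estimated counts because genes that every cell uses are listed at 0 (Gapdh in all 12 libraries, the clathrin heavy chain Cltc in 10) and because many rows jump between 0 and at least 100 within a genotype. Such jumps were found in 4.58% of rows that reach 100 counts for genes with 1 RefSeq transcript, in 13.6%, 16.8% and 19.1% for genes with 2, 3 and 4, and in 19.4% for genes with 5 or more. A count of 0 is reported only as listed at 0, with values per library and no fold. The table has 21769 rows for 21738 distinct symbols, and 5149 rows are 0 in all libraries. There were 25 symbols on several rows (56 rows, 0.319% to 0.567% of a library's counts), which were left out. Of the symbols, 21724 matched a RefSeq gene table of assembly GRCm38.p6, used for transcript numbers, neighbouring symbols and which genes lie near Tet1. Transcript lengths were those of the longest GENCODE transcript per symbol. All sample columns were used.

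Library totals ranged from 5791642 to 10915574, with means of 9505241 in WT, 8962897 in HxD and 7166321 in KO. Reads without molecular identifiers are not independent molecules, so totals limit counting error only. CPM values were computed here from the deposited counts, per the summed counts of the tested genes in a library times its TMM factor. Pearson correlations of log2 CPM were 0.869 to 0.909 within a genotype and 0.834 to 0.901 between genotypes.

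The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust fit) with TMM factors of 0.968 to 1.02 and filterByExpr by group at its minimum count of 10, which kept 11693 genes. All 12 libraries entered 1 fit with genotype as the only term, leaving 9 residual degrees of freedom. HxD against WT, KO against WT and KO against HxD were tested two-sided with a Benjamini-Hochberg adjusted p below 0.05. CPM plus 0.5 was used for log2 values of single libraries. Of 35 gene lists, 33 with at least 5 tested members were tested with camera (limma 3.58.1) on voom values at the preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, fry and ranked edgeR statistics were run beside it. A list score is the median over members of log2 CPM, each gene centred on its mean over all libraries. Scores were compared by an exact permutation test over the 35 splits of 8 libraries, whose smallest p is 0.0286.

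Genes were named by a rule. Tet1, Tet2 and Tet3 are always named. Per comparison the rule takes the 10 higher and 10 lower genes with the smallest p among those past the threshold, with a mean of at least 1 CPM in the higher group and no overlap between the groups' libraries. From each list that passed, or held at least 3 called genes, it takes up to 4 called members, or the 2 with the smallest p where none was called. From other lists it takes up to 2 called members. It also takes the 10 genes with the smallest larger p called in both mutants against WT. Some genes that the rule takes are not reported here.

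The scripts were tested on simulated data with the real means, library sizes and spread. In a simulated KO against WT with 11378 genes, 36.4% of 99 genes changed 2-fold and 73.7% of 99 changed 4-fold were called, with 6 false calls. Simulated HxD against WT, with no changed gene, gave 0 calls. Changed genes were drawn only from those above a minimum expected count. Genes were drawn independently, without any structure that libraries of the real table share, so these rates need not carry over to it.

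Alternatives covered DESeq2 size factors, upper-quartile factors and library size only, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, filters on low counts, only the 8 libraries compared, the replicate number as a block, 1 surrogate variable (sva 3.50.0), markers of neighbouring tissue left out, thresholds of 0.01, 0.1 and an absolute log2 fold change of 0.5, and each library left out in turn. These, the tests, the gene lists and the rule for named genes were fixed before the data were examined. Xist as a covariate was not run because its log2 range of 1.52 over the libraries was below the set minimum of 3. Further alternatives were added after the data were seen: only genes with 1 RefSeq transcript, rows that vary over 8-fold within a genotype left out, repeated symbols kept, the trend on transcript length removed, KO 2 and 3 or WT 3 and HxD 3 left out, and a covariate for libraries 1 and 3 of WT and HxD.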

Results

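Poly(A) RNA from the whole cortex of adult mice was sequenced for 3 genotypes of Tet1, the gene of a dioxygenase that oxidises 5-methylcytosine in DNA. WT, HxD and KO had 4 libraries each. The study's title sets catalytic against non-catalytic functions of TET1, and HxD is also the name of the motif with which TET enzymes bind iron. The design then asks what the cortex expresses differently in HxD, in KO, and between both mutants. Estimated counts per library summed to 8310783 to 10915574 in WT, 7767787 to 10347432 in HxD and 5791642 to 9535409 in KO, so KO held the shallowest libraries. Bc1, a short noncoding RNA of neuronal dendrites, took 4.10% to 7.80% of the counts of a library. Of 21769 rows, 11693 genes passed the filter on low counts. The labels do not say whether libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

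Tet1 was listed at 0 in all 4 WT and all 4 KO libraries, and its estimated counts in HxD 1 to 4 were 1, 0, 63 and 67. These values did not part HxD from WT or from KO beyond the spread between libraries (exact permutation test, two-sided, p = 0.143 for each, where 0.0286 is the smallest p that 4 against 4 libraries allow). The gene did not pass the filter, and its edgeR adjusted p without the filter was 0.996 for HxD against WT, 1 for KO against WT and 0.478 for KO against HxD. The knockout label therefore cannot be checked from this gene. Tet2, a related dioxygenase, stood at 37.9 ± 4.78 CPM in WT, 41 ± 19.2 in HxD and 36.9 ± 10.9 in KO (SD, n = 4). Its log2 fold changes of 0.11 ± 0.33 (SE) in HxD and -0.04 ± 0.33 in KO against WT were below the spread between libraries, and the direct difference between KO and HxD was -0.15 ± 0.33. Tet3 was listed at 0 in all 12 libraries. Gapdh, a glycolytic enzyme that every cell uses, was listed at 0 in all 12 libraries as well, so a 0 in this table does not show that a gene was silent.

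Against WT, edgeR called 57 genes higher and 48 lower in HxD. The DESeq2 Wald test called 84 and 88, and limma-voom 50 and 31. Most of the edgeR calls were large steps between the values in the table. HxD libraries quantified apart from WT and KO would show such steps without any change in the cortex, so the values below are differences in the table. Actb, the gene of beta-actin, stood at 1411 ± 215 CPM in HxD against 0.78 ± 0.489 in WT (SD, n = 4) and was listed at 0 in all 4 KO libraries. Klhdc2, a substrate receptor of a cullin ubiquitin ligase, rose from 1.12 ± 0.0884 to 255 ± 22.7 CPM (log2 fold change 7.81 ± 0.20, adjusted p = 2.9e-09). Map4, which binds microtubules, rose 99.6-fold to 136 ± 25.9 CPM, and Klc1, a kinesin light chain, rose 90.6-fold to 248 ± 30.4 CPM. Gnb2, a G protein beta subunit, reached 383 ± 140.2 CPM in HxD against 2.81 ± 0.968 in WT. Nrsn1, a vesicle membrane protein of neurons, reached 602 ± 117 CPM against 2.12 ± 1.13. Smaller steps were seen for Gas7, a protein of neurite outgrowth, which rose 9.93-fold. Dnm1l, the GTPase of mitochondrial fission, rose 16.7-fold, and Cc2d1b rose 12.7-fold. Their adjusted p-values were 7.6e-07, 6.3e-06 and 6.7e-05.

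Among the genes called lower in HxD, Hspa4, a chaperone of the heat shock protein family, went from 422 ± 26.6 CPM in WT to 3.09 ± 1.12 in HxD (log2 fold change -7.10 ± 0.25, adjusted p = 3.8e-08). Azin2, an antizyme inhibitor of polyamine metabolism, was 26-fold lower, and Fcho2, an early factor of clathrin-mediated endocytosis, was 14.7-fold lower. Prune2 at 109 ± 5.09 CPM in WT, the mRNA decapping factor Edc3 at 41.8 ± 2.83, Plxdc2 at 66.7 ± 6.66 and 4933431E20Rik at 185 ± 17.9 were each listed at 0 in all 4 HxD libraries. Clasp2, which tracks microtubule plus ends, held 2418 to 3815 estimated counts per WT library and 1, 0, 0 and 1 in HxD. Rcan2, a regulator of calcineurin, held 1720 to 3151 in WT and 0, 1, 0 and 0 in HxD. In edgeR's quasi-likelihood test, 105 genes passed at an adjusted p below 0.05, and 473 had an unadjusted p below 0.05 where 584.65 would by chance alone. The 4 libraries of one group lay wholly above those of the other for 407 genes (3.48%), where chance gives 2.86%. Among those called, 90 differed by more than 8-fold, 55 had libraries of both groups at least 8-fold apart throughout, and 22 were listed at 0 in one group. Of the 105, 29 have 1 RefSeq transcript, against 6354 of the 11686 tested genes that matched RefSeq. Beside these steps, HxD differed from both WT and KO in how values repeat over rows for 24 of the 25 symbols that stand on several rows.

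**Figure D1:**
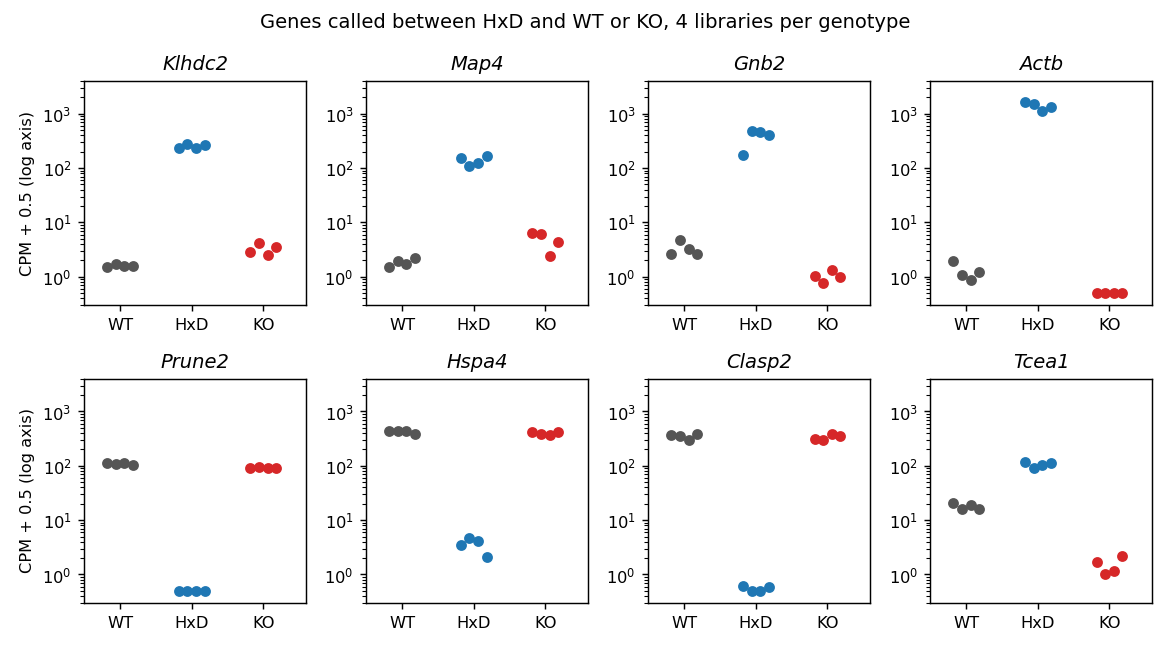
CPM plus 0.5, on a log axis, for 8 genes in the 4 WT, 4 HxD and 4 KO libraries, each point being 1 library. Actb stands at 1411 ± 215 CPM (SD) in HxD and near or at 0 elsewhere, while Hspa4 stands at 3.09 ± 1.12 in HxD and at 422 ± 26.6 in WT. Points at 0.5 are listed at 0.

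Among the gene lists, 5 of 33 passed limma camera in HxD against WT. Subunits of the co-repressor and Polycomb complexes that TET1 binds had a median log2 fold change of 0.11 with 27 of 35 above WT (adjusted p = 0.0208, and 0.152 with an estimated correlation). Mtf2, a Polycomb-like subunit, was the single member past the threshold, both over all genes and adjusted over the list alone. It rose from 0.452 ± 0.18 to 43.4 ± 3.57 CPM on 3 to 7 estimated counts per WT library (adjusted p = 3.7e-07). Immediate early genes, which neuronal activity induces, had a median of 0.30 with 33 of 39 above WT (adjusted p = 0.0208, and 0.933 with an estimated correlation). Their only called member went the other way: Dusp1, a MAP kinase phosphatase, stood at 22.1 ± 10.4 CPM in WT and was listed at 0 in all 4 HxD libraries, and it was also the only one adjusted over the list alone. Neuropeptides and hormones had a median of 0.17 (adjusted p = 0.0486, and 0.604 with an estimated correlation) with 0 of 22 members called by edgeR, 0 adjusted over the list alone and 3 at an unadjusted p below 0.05. Their leading members were the secretory granule proteins Chga, with a log2 fold change of 0.34 ± 0.11, and Scg2, with 0.61 ± 0.24 (adjusted p = 0.585 and 0.999). HxD 3 had the highest neuropeptide score, 0.36, and also the highest score of striatal markers, 1.82, and Scg2 stood at 306 CPM there against 144 to 204 in the other HxD libraries, so tissue next to the cortex is not set apart from this list.

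Clustered protocadherins, the cell surface proteins that give neurons their identity, had a median of -0.13 in HxD with 35 of 53 below WT (adjusted p = 0.0486, and 0.604 with an estimated correlation). No member passed edgeR over all genes, 10 had an unadjusted p below 0.05, and 4 passed adjusted over the list alone. Pcdhga12 stood at 29.6 ± 6.55 CPM in HxD against 61.9 ± 5.72 in WT (adjusted p = 0.15), while Pcdhgb6 went the other way at 62.9 ± 8.78 against 39.6 ± 7.3 (adjusted p = 0.136). Pcdhga12, Pcdhgb6 and the other genes of their cluster share constant exons, so reads between them are uncertain. Myelin genes had a median of -0.23 (adjusted p = 0.0486, and 0.933 with an estimated correlation), and 0 of 31 passed edgeR, 0 adjusted over the list alone and 0 at an unadjusted p below 0.05. Plekhh1 had a log2 fold change of -0.53 ± 0.33 and Pllp of -0.32 ± 0.29. Members of lists that did not pass were called too. Syn2, a synaptic vesicle phosphoprotein, fell from 686 ± 119.8 to 124 ± 65.7 CPM (adjusted p = 0.00224). Lrrtm2, a postsynaptic adhesion protein, rose from 7.15 ± 4.9 to 118 ± 25.3 CPM (adjusted p = 0.0138), a call that was lost in 6 of 32 other settings, without WT 4 among them. Acsl6, an acyl-CoA synthetase, held 38 to 69 estimated counts per HxD library and 0, 1, 0 and 0 in WT. None of the 5 list calls held with an estimated correlation. Without WT 4, whose myelin score stood apart from the other WT libraries, 0 of 33 lists passed camera, and leaving out 1 library took the adjusted p up to 0.0644 for the co-repressor list (WT 4 or HxD 3), 0.48 for immediate early genes (WT 3, WT 4, HxD 2 or HxD 4), 0.156 for protocadherins, 0.189 for neuropeptides and 0.866 for myelin (6, 7 and 7 of the 12 libraries).

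In KO against WT, 5 genes were called higher and 13 lower. Of those higher, 3 were also called higher in HxD against WT, and so were 10 of those lower. How counts were assigned on such rows is not known, so the values below are differences in the table. Cebpd, a transcription factor induced by glucocorticoids and cytokines, rose 2.86-fold from 7.84 ± 1.45 to 22.5 ± 3.89 CPM (SD, n = 4, adjusted p = 0.0453). Dnm1l rose 2.97-fold, to 23.1 ± 6.04 CPM. Klhdc2, at 2.81 ± 0.755 CPM in KO against 1.12 ± 0.0884 in WT, rose from a low level. So did Mtf2, at 1.76 ± 0.455 against 0.452 ± 0.18, and Cnot2, a subunit of the CCR4-NOT deadenylase, at 5.73 ± 3.12 against 0.845 ± 0.219. Adjusted p-values for these 4 genes were 0.0341, 0.0242, 0.0251 and 0.0418. Tcea1, a transcription elongation factor, fell from 17.4 ± 2.55 to 1.02 ± 0.543 CPM (log2 fold change -4.12 ± 0.30, adjusted p = 5.1e-04). Dnajc13, an endosomal co-chaperone, fell 8.99-fold to 0.869 ± 0.0675 CPM. Genes listed at 0 in all 4 KO libraries included Ylpm1, with 52 to 162 estimated counts per WT library, and Trip4, a transcriptional coactivator, with 51 to 125. Klc1 held 12 to 41 per WT library, and the cadherin Cdh9 held 16 to 23. The GTPase-activating protein Arhgap29 at 4.18 ± 2.19 CPM in WT and the Rab exchange factor Dennd6b at 3.69 ± 1.36 were likewise listed at 0 in KO. The same held for Csad, an enzyme of taurine synthesis, at 1.55 ± 0.448 CPM in WT and for Mlxip, a glucose-responsive transcription factor, at 1.34 ± 0.557.

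The edgeR test called 18 genes in KO against WT, 10 of them listed at 0 in one group, and 1108 genes had an unadjusted p below 0.05 against 584.65 by chance. Libraries did not overlap for 842 genes (7.20%, against 2.86% by chance). The count rests on the tool: limma-voom called 0 genes with 1137 at an unadjusted p below 0.05, the edgeR fit on these 8 libraries alone called 0 with 1171, and the DESeq2 Wald test called 288. Of the genes that rose, Cebpd lost its call in 21 of 33 other settings, Klhdc2 in 13 of 33, and Mtf2, Dnm1l and Cnot2 in 15, 17 and 20 of 32, while without WT 4 the count was 35.

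Genes of the glucocorticoid response were higher in KO than in WT, with 18 of 20 above WT and a median log2 fold change of 0.52 (limma camera, adjusted p = 1.5e-09, and 0.0785 with an estimated correlation). Cebpd alone passed over all genes, and 8 passed adjusted over the list alone. The list score per library was 0.42 ± 0.21 in KO and -0.18 ± 0.16 in WT (SD, n = 4, exact permutation test, two-sided, p = 0.0286, the smallest possible), although KO 1 at 0.74 lay apart from the other KO libraries at 0.30 to 0.32. Fry gave the list an adjusted p of 0.0173. Over the 33 lists, the lowest adjusted p of such score tests was 0.314. Clock genes were higher as well, with a median of 0.35 and 14 of 18 above WT (adjusted p = 9.4e-04, and 0.409 with an estimated correlation). None of them passed edgeR over all genes, 6 had an unadjusted p below 0.05 and 5 passed adjusted over the list alone. Dbp, an output gene of the clock, stood at 211 ± 27 CPM in KO against 112 ± 33.8 in WT (adjusted p = 0.199), and the clock repressor Bhlhe41 at 94.7 ± 8.05 against 63.3 ± 14.9 (adjusted p = 0.199). Immediate early genes had a median of 0.67 with 30 of 39 above WT (adjusted p = 2.8e-07, and 0.409 with an estimated correlation). Among them, 0 passed edgeR over all genes, 9 had an unadjusted p below 0.05 and 3 passed adjusted over the list alone. The phosphatase Dusp5 stood at 44.7 ± 7.53 CPM in KO against 16 ± 4.26 (adjusted p = 0.0785), and Tiparp, an ADP-ribosyltransferase, at 51.7 ± 10.9 against 22.3 ± 5.36 (adjusted p = 0.0817).

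**Figure D2:**
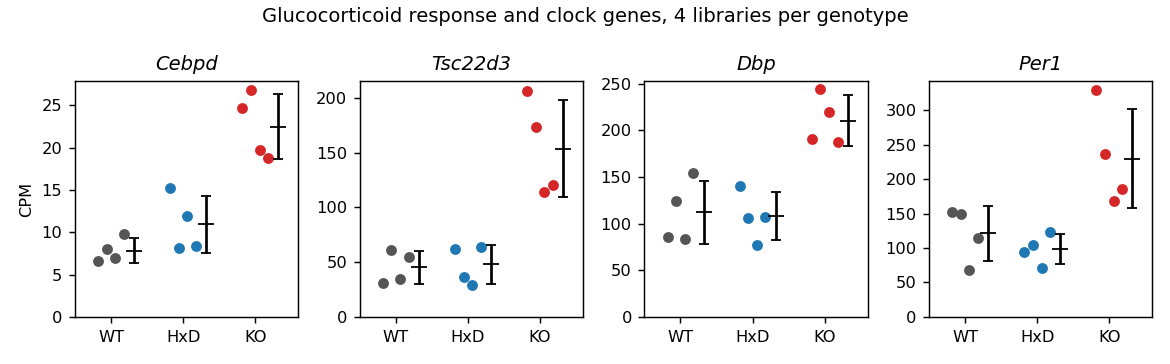
CPM of 4 genes of the glucocorticoid response and clock lists in each library, on linear axes from 0, with the mean and SD of each genotype beside the points. Tsc22d3 stands at 153 ± 44.3 CPM (SD) in KO and 45.3 ± 14.9 in WT, and Dbp at 211 ± 27 and 112 ± 33.8.

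Cytosolic ribosomal protein genes had a median of 0.29 in KO with 68 of 72 above WT (adjusted p = 4.5e-12, and 0.409 with an estimated correlation). Per library the scores were 0.21 ± 0.24 in KO and -0.07 ± 0.24 in WT, and the groups overlapped (exact permutation p = 0.143). By edgeR 0 members passed over all genes, 0 adjusted over the list alone and 11 at an unadjusted p below 0.05. Rpl28 stood at 188 ± 14.3 CPM against 144 ± 20.2. Nuclear-encoded respiratory chain genes had a median of 0.22 with 50 of 57 above WT (adjusted p = 5.2e-08, and 0.409 with an estimated correlation). Of these, 0 passed edgeR, 0 adjusted over the list alone and 9 had an unadjusted p below 0.05. Uqcr10, a subunit of cytochrome bc1 complex, stood at 89.4 ± 15.6 CPM against 62 ± 8.69, while the complex I subunit Ndufb10 was lower at 5.83 ± 0.384, with 1033, 77, 58 and 1213 estimated counts in WT 1 to 4. KO also held the libraries with the steepest trend on transcript length, and with that trend removed the medians were 0.17 for the ribosomal list and 0.10 for the respiratory list (adjusted p = 2.7e-08 and 0.00314).

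Astrocyte genes had a median of 0.28 in KO against WT with 19 of 22 above WT (adjusted p = 0.00268, and 0.409 with an estimated correlation). The astrocyte connexin Gjb6 stood at 110.2 ± 20.4 CPM against 77.5 ± 13.6, and the thyroid hormone transporter Slco1c1 at 109.8 ± 14.1 against 62.8 ± 7.48. Myelin genes had a median of 0.30 with 26 of 31 above WT (adjusted p = 9.4e-04, and 0.725 with an estimated correlation), led by Qdpr with a log2 fold change of 0.69 ± 0.25 and Mobp, a structural protein of myelin, with 0.62 ± 0.38. Glutamate receptor and postsynaptic density genes were lower, with 31 of 43 below WT and a median of -0.36 (adjusted p = 0.00665, and 0.0785 with an estimated correlation). Grin2b, an NMDA receptor subunit, stood at 549 ± 88.2 CPM against 971 ± 193, and Lrrtm2 held 1 to 2 estimated counts per KO library against 4, 111, 91 and 65 in WT 1 to 4. Lrrtm2 is also a row at a level of its own in HxD. With its wide range within WT, it is weak support for a change of the list. Leaving out KO 3 gave the receptor list an adjusted p of 0.0735. Striatal markers, for a tissue next to the cortex, had a median of -0.60 (adjusted p = 0.0364, and 0.725 with an estimated correlation). The opioid precursors Penk and Pdyn led them with -0.99 ± 0.41 and -0.63 ± 0.30, and the list lost its call without WT 3, WT 4, KO 2 or KO 3 (adjusted p up to 0.184). No member of these 4 lists passed edgeR over all genes, and adjusted over the list alone 0, 0, 2 and 0 did. At an unadjusted p below 0.05 there were 5, 1, 6 and 1. In WT and HxD, libraries 1 and 3 differed from libraries 2 and 4, with a median of -0.81 for the myelin list and 0.89 for the striatal list between these sets. Between them 8 of 33 lists passed camera and 0 with an estimated correlation, and those that passed included immediate early and clock genes, lower in libraries 1 and 3 (adjusted p = 0.00673 and 0.00409, and 0.809 and 0.542 with an estimated correlation). With that split as a covariate, the adjusted p for KO against WT was 1.0e-04 for immediate early genes and 0.028 for clock genes, and for KO against HxD it was 0.519 for immediate early genes and 0.0231 for clock genes. With the same covariate, the adjusted p for KO against WT was 0.986 for myelin and 0.46 for striatum. The covariate places all KO libraries with libraries 2 and 4, so KO is compared with the level of that side. That side holds WT 4 with its myelin score of 0.77, so whether the split accounts for the myelin call is not shown.

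**Figure D3:**
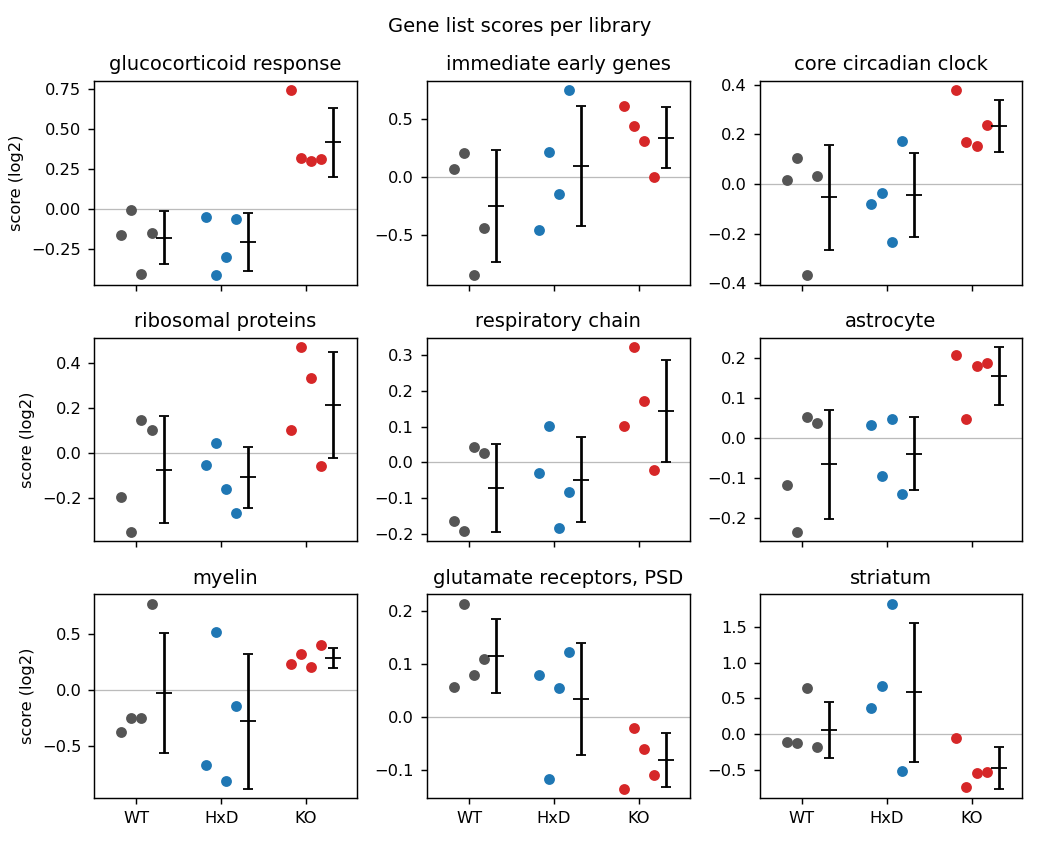
Scores of 9 gene lists per library, each point being 1 library, on a log2 scale, with the mean and SD of each genotype beside the points. In the glucocorticoid panel the 4 KO libraries lie at 0.30 to 0.74, above all WT and HxD libraries. In the myelin panel WT 4 lies at 0.77 while the other WT libraries lie at -0.37 to -0.25.

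Between the mutants, 52 genes were higher and 67 lower in KO than in HxD by edgeR, where the DESeq2 Wald test called 397 (165 higher and 232 lower). Most were the genes on which HxD stood apart: 86 of the 119 were also called in HxD against WT. Hspa4 stood at 398 ± 23.8 CPM in KO (log2 fold change 7.02 ± 0.25 against HxD), close to its WT level, and Azin2 at 65.6 ± 3.12 and Fcho2 at 44.5 ± 5.65 likewise. Syn2 was 3.57-fold higher in KO and lost this call in 6 of 32 other settings. Dusp1 stood at 90.1 ± 20.8 CPM in KO. Tcea1 fell 106-fold, Dnajc13 94.5-fold, Gas7 16.4-fold and Map4 31.6-fold. Among 41 genes whose HxD libraries lay at least 8-fold from all libraries of both other genotypes, 19 were higher and 22 lower in HxD. KO had 1 such gene, Ylpm1, and WT had 0. In edgeR's test 1358 genes had an unadjusted p below 0.05 against 584.65 by chance, 37 of the 119 were listed at 0 in one group, and libraries did not overlap for 887 genes (7.59%, against 2.86% by chance).

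Apart from those steps, Tsc22d3, a glucocorticoid-induced leucine zipper protein, was 3.19-fold higher in KO than in HxD, at 153 ± 44.3 against 48.1 ± 17.6 CPM (adjusted p = 0.0397). Uqcr10 was 1.77-fold higher (adjusted p = 0.0255). Fdft1, the squalene synthase of cholesterol synthesis, stood at 83.7 ± 32.5 CPM in KO and 11 ± 7.62 in HxD (adjusted p = 0.0233), and WT at 56.7 ± 24.7 lay nearer to KO. Tsc22d3 lost its call in 18 of 32 other settings, Uqcr10 in 12 and Fdft1 in 9. The glucocorticoid list had a median of 0.64 with 1 of 20 called and 10 adjusted over the list alone (adjusted p = 2.0e-07, and 0.273 with an estimated correlation). Its scores were 0.42 ± 0.21 in KO and -0.20 ± 0.18 in HxD (SD, n = 4, exact permutation p = 0.0286). Clock genes had a median of 0.31 with 0 called by edgeR, 7 at an unadjusted p below 0.05 and 6 adjusted over the list alone. Dbp stood at 108 ± 25.6 CPM in HxD and the period gene Per1 at 229.9 ± 72.3 in KO against 98.1 ± 21.8 in HxD. Immediate early genes had a median of 0.38 with 1 called and 4 adjusted over the list alone. The called gene was Dusp1, itself one of the steps of HxD. Adjusted p-values were 0.00169 for the clock list and 0.0334 for immediate early genes, and 0.508 and 0.72 with an estimated correlation. The immediate early list lost its call without HxD 1, HxD 3, KO 1 or KO 2 (adjusted p up to 0.328).

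Ribosomal protein genes had a median of 0.33 in KO against HxD, with 69 of 72 above HxD and Rps3 at 495 ± 20.5 against 392 ± 24.2 CPM and Rpl13 at 529 ± 88.8 against 401 ± 46.1. Respiratory chain genes had a median of 0.20. Myelin genes had 0.58 with 30 of 31 above HxD, led by Plekhh1 with a log2 fold change of 0.73 ± 0.33 and the oligodendrocyte protein Opalin with 1.0 ± 0.44. Astrocyte genes had a median of 0.29 and a mean of -0.06, which differ in sign because Acsl6 fell from 38 to 69 estimated counts per HxD library to 1, 0, 0 and 0 in KO. Striatal markers had -1.06 with 15 of 16 below HxD, and the adenosine receptor Adora2a stood at 6.21 ± 2.49 CPM against 43.5 ± 32.6 and Penk at 35.1 ± 11.1 against 131 ± 75.6. Heat shock and folding genes had -0.18, with the chaperones Calr at -0.41 ± 0.12 and Hspd1 at -0.20 ± 0.07. Camera gave these 6 lists adjusted p-values of 3.0e-11, 6.4e-05, 6.9e-07, 0.0209, 0.00131 and 0.0209. With an estimated correlation the adjusted p was 0.508 for each of the 6. By edgeR, 1 respiratory and 1 astrocyte gene were called over all genes and 0 of the other lists, and adjusted over the list alone the counts were 0, 1, 0, 4, 1 and 0. At an unadjusted p below 0.05 they were 26, 8, 1, 8, 8 and 3. Striatal scores ran from -0.52 in HxD 4 to 1.82 in HxD 3. With the split of WT and HxD libraries as a covariate the myelin list had an adjusted p of 0.052 and the striatal list of 0.0231. The striatal and respiratory lists each lost their call in 4 of 23 other settings. The astrocyte list lost its call without HxD 2 or HxD 4 (up to 0.154) and the heat shock list without HxD 2, HxD 4, KO 2 or KO 3 (up to 0.328).

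Against the shared WT libraries, 3 genes rose in both mutants (Klhdc2, Mtf2 and Dnm1l), and 10 went in opposite directions. The calls of all 3 in KO against WT were lost with a covariate for libraries 1 and 3 of WT and HxD, with limma-voom and on the 8 libraries alone. All 10 were higher in HxD and lower in KO: Tcea1, Dnajc13, Klc1, Mlxip, Dennd6b, Csad, Ylpm1, Arhgap29, Polr1a, the largest subunit of RNA polymerase I, and Tmem176b. Of these, Klc1, Mlxip, Polr1a and Tmem176b, like Klhdc2 and Mtf2, are among the 41 rows at a level of their own in HxD. Missing that 8-fold gap does not clear the others of such steps. HxD lay above WT without overlap for Tcea1 (92.4 to 116 against 15.2 to 20.5 CPM) and Dennd6b (33.5 to 51 against 1.71 to 4.61). The same held for Ylpm1 (83.5 to 142 against 5.21 to 19.7). Polr1a stood at 43 ± 14.5 CPM in HxD and 0.516 ± 0.146 in WT, and Tmem176b at 20.1 ± 5.45 and 0.581 ± 0.284, and both were listed at 0 in KO. Their calls in KO against WT were lost in 15 of 32 and 19 of 31 other settings. Mcfd2 was the other gene called lower in KO, named here after its value was seen because the list of 18 is otherwise complete. Independent lists would share 0.0244 higher, 0.0534 lower and 0.0839 opposite genes, and 20 simulated pairs of unchanged groups against the same WT libraries shared 0 in either direction. With the WT libraries split in pairs, one pair for each contrast, 0 to 2 genes had the same sign and 7 to 12 the opposite. Across genes, which are not replicates, the fold changes correlated with Pearson's r of 0.169 and Spearman's coefficient of 0.264. Leaving out 1 library gave r of 0.165 (without KO 3) to 0.344 (without WT 4), with a jackknife SE of 0.216. Simulated unchanged groups gave r of 0.151 ± 0.0319 (SD of 20 draws), and the split WT libraries gave -0.0713 to 0.00465. The covariance was 0.145 against 0.0644 ± 0.0151 simulated, and -0.103 to 0.00618 with split WT libraries. The simulated groups were drawn around the observed WT means, so they leave out the error of those means that both contrasts share. Their shared calls, r and covariance therefore do not set the level without change. Regroupings of the 12 libraries ran higher, with r of 0.339 to 0.643 and a covariance of 0.18 to 0.46.

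Genes near Tet1 could carry linked DNA of the strain in which an allele was made. Within 20 Mb of Tet1 lay 2 of the 105 genes called in HxD against WT, Celf5 and Hmg20b, 0 of the 18 in KO against WT and 1 of the 119 in KO against HxD, Celf5. Of all tested genes with a position, 1.94% lay there (Fisher's exact test, two-sided, p = 1, 1 and 0.732).

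Lists that passed camera in no comparison are given with their adjusted p for HxD against WT, KO against WT and KO against HxD. For TET and DNA methylation enzymes these were 0.859, 0.631 and 0.928, for developmental transcription factors under Polycomb control 0.234, 0.0989 and 0.83, and for imprinted genes 0.361, 0.424 and 0.113. Neuronal lists gave 0.234, 0.0519 and 0.717 for synaptic vesicle genes, 0.789, 0.791 and 0.993 for GABA receptors and 0.361, 0.424 and 0.993 for voltage-gated channels. Layer markers of excitatory neurons gave 0.859, 0.791 and 0.993, and interneuron markers gave 0.234, 0.788 and 0.153. Other cell types gave 0.859, 0.999 and 0.993 for oligodendrocyte precursors, 0.413, 0.285 and 0.83 for microglia, 0.746, 0.424 and 0.281 for vessels and 0.358, 0.301 and 0.981 for blood. Neighbouring tissues gave 0.361, 0.364 and 0.0752 for hippocampus, 0.641, 0.791 and 0.56 for choroid plexus, 0.413, 0.606 and 0.981 for meninges and 0.96, 0.866 and 0.981 for thalamus and hypothalamus. Interferon genes gave 0.122, 0.999 and 0.249, cholesterol synthesis 0.15, 0.999 and 0.407, cell cycle genes 0.859, 0.424 and 0.32, and genes of X inactivation and the Y chromosome 0.96, 0.381 and 0.3. Germline genes had 4 of 44 members tested, below the minimum of 5, and 0 of the 13 genes of the mitochondrial genome were in the table.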

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

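The tests on HxD rows and on the split of WT and HxD libraries were chosen after the result was seen, as was the rule that a median within its spread leaves the circadian test open. Dixon's test looked for 1 library apart from the other 3 in 228 groups of 4, where chance alone gives 11.4, and it found 16.

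In WT, library 4 stood apart on its myelin score and on 4 single genes. Its myelin score was 0.77 against -0.37 to -0.25 in the others, the myelin gene Mobp stood at 73.6 CPM against 28.0 to 32.9, the astrocyte connexin Gjb6 at 97.9 against 69.3 to 71.8, and the clock repressor Bhlhe41 at 85.6 against 55.3 to 56.9. Tmem176b held 1.003 CPM there against 0.381 to 0.486. WT 3 had a striatal score of 0.64 against -0.18 to -0.12 and Adora2a, a receptor of striatal neurons, at 51.3 CPM against 3.99 to 11.04. WT 2 held the granule protein Chga at 253 CPM against 217 to 222 and the co-chaperone Dnajc13 at 2.95 against 9.47 to 9.82.

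In HxD, library 1 stood apart on Acsl6, at 4.09 CPM against 6.73 to 7.15, and on the mitochondrial chaperone Hspd1, at 235 against 207 to 211. HxD 4 held Fcho2 at 2.93 CPM against 2.69 to 2.73. Lists that passed camera in no comparison were not put to Dixon's test. On such lists, HxD 1 had a hippocampus score of 1.28 against -0.08 to 0.15 in the other HxD libraries. HxD 3 had a thalamus and hypothalamus score of 1.35 against -0.96 to -0.08. Both were picked after their values were seen. In KO, library 1 had a glucocorticoid score of 0.74 against 0.30 to 0.32, a heat shock score of 0.14 against -0.12 to -0.08, and Adora2a at 9.93 CPM against 4.81 to 5.30. KO 4 held Qdpr, a pterin reductase, at 437 CPM against 252 to 256.

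The mutants differed from each other in the direct test by 119 genes and, at camera's preset correlation, by 9 gene lists. With an estimated correlation 0 of 33 lists passed. Against WT, 10 genes were called in opposite directions. Other splits of the 8 libraries reached at most 2 genes for KO against HxD, and 1 of 35 splits, the real one, gave as many. That is the smallest share that 35 splits allow (0.0286), with no adjustment over the comparisons, so chance is not excluded. Of the 119 genes, 86 were also called in HxD against WT. Splits that mix HxD with KO would lose the steps of HxD, whatever set them. For KO against WT the real split with 18 genes was also 1 of 35, with 2 as the highest other. For the 3 genes that rose in both mutants, 1 of 100 regroupings of the 12 libraries gave as many, the real one, with 2 as the highest other. For HxD against WT with 105 genes, 2 of 35 splits gave as many and the other gave 269, so chance is not excluded by this count. That split sets libraries 1 and 3 of WT and HxD against libraries 2 and 4, which points to a structure of the samples. Gene list counts did not exclude chance: 20 of 35 splits gave as many as the 5 of HxD against WT (highest other 11), 5 of 35 as many as the 9 of KO against WT (highest other 12), and 4 of 35 as many as the 9 of KO against HxD (highest other 13). The correlation of 0.169 was the lowest of 100 regroupings, so that 100 gave as large a value, with 0.643 as the highest other. Without WT 4 the correlation was 0.344, above the lowest of the other regroupings at 0.339 and below the next at 0.346. That fit held 1 library fewer than the regroupings, so whether the low standing rests on WT 4 is not shown. All 99 others also had a larger covariance, 0.18 to 0.46 against 0.145. Simulated unchanged groups had a smaller covariance, at most 0.0928, while their r of 0.0872 to 0.218 spanned the real value. They were drawn around the observed WT means, so the error of those means that both contrasts share was left out. The simulation therefore cannot set the level without change.

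Actb, Klhdc2, Prune2 and Clasp2 belong to a first pattern, 41 rows at a level of their own in HxD. On the 25 symbols that stand on several rows, HxD parted from both WT and KO in 24: either HxD alone repeated 1 value over the rows (16) or WT and KO did and HxD did not (8). A candidate explanation is that the HxD libraries were quantified apart from WT and KO and joined by symbol, which would set such levels without any change in the cortex. Reads handed to a neighbouring symbol are argued against, since 0 of 41 rows had a neighbour with the opposite step. Counting 1 of several transcripts stays open: 56.1% of these rows have several RefSeq transcripts against 45.6% of others (Fisher's exact p = 0.209). Among all genes called in HxD against WT, 29 of 105 had 1 RefSeq transcript, against 6354 of 11686 tested genes. That was 5 of 18 in KO against WT and 42 of 119 in KO against HxD. These shares were lower among called genes in each comparison, a difference that was not tested. An effect of the HxD genotype on the genes of the 41 rows also stays open, as untested. It would not by itself set whether 1 value repeats over the rows of a symbol.

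Higher glucocorticoid genes in KO, led by Cebpd and Tsc22d3, form a second pattern, whose call by camera was lost with an estimated correlation (adjusted p = 0.0785). The adjusted p-values that follow are at the preset correlation. A trend with transcript length is argued against: the list's median lay at percentile 100 among 10000 random lists matched on length, and with the trend removed the adjusted p was 2.5e-09. Neuronal activity at collection is argued against as the whole cause, since with the immediate early gene score as covariate the adjusted p was 8.8e-07 and the median went from 0.52 to 0.49. A later circadian phase may account for it and stays open, since all 8 genes that share the phase of Dbp were above 0 but the 4 in opposite phase had a median of -0.052 with 2 on each side. Stress or handling before collection and the KO genotype itself stay open as well, as untested.

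Libraries 1 and 3 of WT and HxD against libraries 2 and 4 form the third pattern, of 269 genes, 113 higher and 156 lower. Nr2f2, a transcription factor of caudal cortex and some interneurons, stood at 43.3 to 145 CPM in libraries 1 and 3 and 7.15 to 15.5 in libraries 2 and 4, with Stac2 at 96.4 to 112 and 313 to 333 and the upper-layer gene Lamp5 at 94.2 to 228 and 364 to 510, all 3 picked after their values were seen. KO libraries, which were not used to choose the genes, scored -0.59 to -0.27, on the side of libraries 2 and 4 at -0.74 to -0.50 and not of libraries 1 and 3 at 0.76 to 1.26. A trend with transcript length is argued against (mean difference -0.0385, with overlapping sets), while neighbouring tissue stays open: 0 of 5 lists parted the sets, yet camera put meninges and striatum higher in libraries 1 and 3 (adjusted p = 0.00378 and 0.00409, and 0.795 for each with an estimated correlation). Another part of the cortex could also account for it and was not tested.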

How the results depend on the processing

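The settings on transcripts, rows, length, repeated symbols, pairs of libraries and the split of WT and HxD were chosen after seeing the data. With other scaling factors the edgeR counts of called genes stayed at 105, 18 and 117 to 120 for HxD against WT, KO against WT and KO against HxD. The DESeq2 Wald test called 172, 288 and 397 genes and 49 in both mutants with the same sign, against 3 with edgeR. In KO against WT limma-voom called 0 (1137 at an unadjusted p below 0.05), and 0 were called on the 8 libraries alone (1171). Both also gave 0 shared genes. At an adjusted p of 0.01 there were 10 genes in KO against WT and 0 shared, and at 0.1 there were 33 and 8. Fewer genes tested, those with 1 RefSeq transcript, gave 29, 2, 43 and 0 shared. Without rows that vary over 8-fold within a genotype, KO against WT gave 30 and 9 were shared. With the covariate for libraries 1 and 3 these were 9 and 0, and without KO 2 and 3 there was 1 shared. The cause of these changes was not tested. Leaving out 1 library gave 12 (without WT 2) to 35 (without WT 4) genes in KO against WT and 1 (without WT 1) to 7 (without WT 4) shared.

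With an estimated correlation 0 of 33 gene lists passed camera in each comparison and with fry 1 in each (the co-repressor list in HxD, the glucocorticoid list in both others). Ranked edgeR statistics passed 6, 8 and 12 lists. On ranks the calls were lost for protocadherins in HxD against WT, glutamate receptors in KO against WT and immediate early genes in KO against HxD (adjusted p = 0.0584, 0.0814 and 0.085). Lists that passed on ranks only were heat shock and striatum in HxD against WT (0.0153 and 0.00319) and hippocampus, imprinted genes, interneurons and vessels in KO against HxD (0.0133, 0.0357, 0.0264 and 0.0327). For HxD against WT 1 list passed without variable rows, 2 with the length trend removed, 2 without WT 3 and HxD 3, and 0 (without WT 4) to 7 (without HxD 1) with 1 library left out. Its myelin list had adjusted p-values of 2.9e-07 (without HxD 2) to 0.866 (without HxD 3), and without WT 4 its direction turned (0.581). Pllp ran from -0.58 (without HxD 2) to 0.00864 (without WT 4). Tet2, not called, turned sign: in HxD against WT it was -0.12 without WT 3 and HxD 3 and -0.15 (without HxD 4) to 0.30 (without HxD 1). In KO against WT it was 0.0711 with the length trend removed, 0.21 without KO 2 and 3, and -0.16 (without KO 1) to 0.15 (without KO 3). In KO against HxD it was 0.10 without KO 2 and 3, 6.6e-04 without WT 3 and HxD 3, and -0.35 (without HxD 1) to 0.10 (without HxD 4). The correlation of fold changes was -0.0359 as the mean over 6 splits of WT, which removes the shared controls.

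Over all tested genes, same-numbered libraries did not pair 1 to 1: they correlated at -0.0708 to 0.0779, and 4 of 12 correlated best with their own number. Numbers 1 and 3 still parted from numbers 2 and 4 in both WT and HxD, so a factor that follows the numbers is not ruled out. With the replicate number as a block, HxD against WT called 74 genes, KO against WT 5 and KO against HxD 95. In that setting KO against HxD called 14 lists. Of the alternative values for named genes, 3363 kept direction and side of the threshold, 211 lost the call, 32 gained it and 13 turned. Tet1 did not pass the filter, and fitted without the filter it was not called (adjusted p = 0.996, 1 and 0.478). Thinned at random 1 time to 5760519, the smallest total once rows of repeated symbols are left out, the data gave 104, 14 and 121 genes. Counts of similar size were thus also reached at equal depth. Whether the same genes were called was not tested, nor was the effect of low depth in all libraries.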

Other observations

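The clock genes named here and the split of libraries were chosen after the result was seen. The length-matched test of the glucocorticoid list was set before its result. When those of the ribosomal and respiratory lists and the test on thinned counts were set is not recorded.

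In KO against WT the clock repressor Nr1d2 had a log2 fold change of 0.46 ± 0.15 (SE), Per1 of 0.92 ± 0.29, Per3 of 0.36 ± 0.18 and Nr1d1 of 0.37 ± 0.17, while the activator partner Npas2 had -0.36 ± 0.14. None passed edgeR's test over all genes (adjusted p = 0.331, 0.327, 0.588, 0.544 and 0.433).

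Between libraries 1 and 3 and libraries 2 and 4 of WT and HxD, single genes differed, while the layer markers of excitatory neurons and the interneuron markers did not pass camera as lists (adjusted p = 0.922 and 0.475). The adhesion gene Cdh13 had a log2 difference of 0.97 ± 0.12 (SE) and the calcium sensor Hpcal1 of 1.93 ± 0.21, both higher in libraries 1 and 3. Rgs4, a regulator of G protein signalling, had -1.02 ± 0.11 and Igfbp4, which binds insulin-like growth factors, -1.17 ± 0.14. The edgeR adjusted p-values were 0.00623, 0.00481, 0.00454 and 0.00567. Wfs1, Crym, Calb1 and Rspo1 did not pass (adjusted p = 0.0717, 0.203, 0.0804 and 0.1). In KO, Rgs4 stood at 546 to 706 CPM, within or near the 600.3 to 776 of libraries 2 and 4 and above the 294 to 397 of libraries 1 and 3.

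Ribosomal protein genes had a median of 0.29 in KO against WT, above 10000 of 10000 random lists matched on transcript length, whose middle 95% ran from 0.05 to 0.19. The respiratory chain list at 0.22 lay at percentile 97.9 of its own matched lists. Thinned to the smallest library total, these lists had adjusted p-values of 1.4e-11 and 2.3e-08 by camera at the preset correlation. Without thinning, the adjusted p was 0.409 for each with an estimated correlation, and exact permutation tests of their scores gave p = 0.143 and 0.0857.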
